A study of Mus musculus with 2 samples.

How the data were processed

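Sorting of embryonic cells gave 2 samples, 1 of Venus-positive and 1 of Venus-negative cells, each with 1 one-colour Affymetrix Mouse Genome array. Groups were taken from the cell type given in the labels. According to the labels' protocols, biotinylated cRNA was prepared from 100 ng of total RNA by the manufacturer's standard procedure. The number of embryos, their stage and the sorting gates are not given in the sources used here.

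The deposited table holds 1 linear intensity per probe set and array, which the authors computed with MAS5, per the submitters' processing notes. MAS5 summarises the perfect-match probes of a probe set after correction with the mismatch probes. The version, the scaling target and the detection calls are not given in the sources used here. All 45101 values per array were above 0, from 0.015 to 14853 on the Venus-negative array and from 0.022 to 13442 on the Venus-positive array. Means trimmed by 2% at each end were 133 and 109 and medians 26.5 and 19.0, so the trimmed means over all probe sets were not at a shared value. The number of arrays, 1 per group, limits the precision. There is no estimate of the spread between samples, and no p-value between the fractions was computed.

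The 64 control probe sets (names starting with AFFX) were set aside. Of the other 45037 probe sets, 34945 were paired with 1 gene symbol, 932 with several and 9160 with none in the platform annotation, and only the first kind was used for genes. Gene identifiers matched the RefSeq table of assembly GRCm38.p6 for 34741 of the probe sets with 1 symbol, and no symbol differed from it. No coordinates are printed, since the table of values names no genome build. The floor was the median of all non-control signals of both arrays, 22.5, and lower signals were set to it before taking log2. The floor stands in for detection calls, and 52.7% of Venus-negative and 47.3% of Venus-positive probe sets reached it. A gene was measured if a probe set reached the floor on at least 1 array, and the probe set with the highest mean log2 signal stood for it. The log2 ratio is Venus-positive over Venus-negative. Where the dimmer side was below the floor the fold is a lower bound, written "at least". This applied to 1211 measured genes on the Venus-positive and 280 on the Venus-negative array.

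The main scale was the deposited one. Because the median log2 ratio of all measured genes was -0.33, ratios relative to this median are given as well. Counts used fixed sizes of 2-fold and 4-fold and are no tests. The 31 gene lists, the sizes, the rule for named genes and 7 alternatives were fixed before the data were examined. The median of each list's measured members was placed among the medians of 10000 random lists of measured genes, matched in number within 20 bins of mean log2 signal. A percentile describes these 2 arrays and is not evidence across animals. Lists share some members, and the cartilage matrix list includes Col2a1, whose reporter defined the sort. Named genes were Col2a1 and Sox9, the 15 genes with the largest log2 ratio in each direction among those with a conventional symbol whose measured probe sets all lay on 1 side of 0, and the 4 members of each list with the largest absolute log2 ratio, ranked on the deposited scale with the floor applied. A few further members were named for contrast after their values were seen, namely Ucma, Cilp, Sox6, Arid5b, Lmx1b, Foxn3, Foxp1, Col10a1, Col1a1, Col1a2, Hspa5, Slc2a1, Fgfr2, Fgf18, Frzb, Sfrp5, Hbb-y, Tagln, Rgs5, Col3a1, Col14a1, Scx, Gdf5, Fmod and Fos.

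The alternatives were centring on the median ratio, quantile normalization, floors at the 25th and 75th percentiles, no floor with log2(signal + 16), the mean over a gene's probe sets, and leaving out probe sets named _x_at or _s_at, which can match several transcripts. Scaling to the hybridisation controls was added after seeing the data, as were the list percentiles under each alternative, drawn anew from the genes measured there. A value was taken as kept when it moved by less than 0.35, the pooled standard deviation of log2 ratios between probe sets of 1 gene, or, for counts, by less than 1.5 times.

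The procedure was tested on simulated data, in which the second array was the Venus-negative array dimmed by the observed shift, with noise of that size per probe set, and 200 genes at or above 4 times the floor were changed. All 50 genes in each group, raised or lowered by 4-fold or 8-fold, passed the 2-fold size among 11459 measured genes. Of 11259 unchanged genes, 1 passed as higher and 237 as lower on the deposited scale, against 14 and 14 after centring. The dimmer array, together with this noise, thus moves genes into the lower class. The noise was taken from probe sets of this pair of arrays and holds no error between samples, so these counts may be too favourable. Of 200 random lists of unchanged genes 8 fell outside the central 95% of matched lists, and all 200 lay above it when raised by 0.5 on the log2 scale. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.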

Results

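Gene expression was measured in cells sorted from embryos of Col2a1-Venus transgenic mice on a C57BL/6 background. Per the series description, chondrocytes, the cells that make cartilage, carry the label Venus, a modified green fluorescent protein, in these mice. Col2a1 is the gene of the main cartilage collagen. Cells were separated by fluorescence-activated cell sorting into a Venus-positive and a Venus-negative fraction, and total RNA of each fraction was hybridised to 1 Affymetrix Mouse Genome array. The comparison asks which genes distinguish the Venus-positive from the Venus-negative fraction. The latter need not represent all other cells of the embryo. Each fraction was measured once, so the values below have no replicate error, no test across samples was possible, and every difference describes these 2 arrays. The disagreement between probe sets of 1 gene shows only how far probes differ within this pair of arrays. All probe sets share the same 2 RNA samples, so it holds no error between samples and does not replace replicates. Among 5445 genes with several measured probe sets, the median standard deviation of their log2 ratios was 0.21.

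Of 18193 genes with a probe set of their own, 11789 had a signal at or above the floor of 22.5 on at least 1 array, and 10298 of these were above it on both. The log2 signals of these 10298 genes correlated with r = 0.92 across genes, which are not independent replicates. The Venus-positive array was dimmer. Its trimmed mean signal was 109 against 133 on the Venus-negative array, and the median log2 ratio of Venus-positive over Venus-negative signal was -0.33, a 1.26-fold lower signal for the typical gene. Folds below are on the deposited scale, and "relative" log2 ratios have this median subtracted. On the deposited scale 329 genes were at least 2-fold higher and 1368 at least 2-fold lower in Venus-positive cells, and 103 and 264 genes differed by at least 4-fold. Relative to the median gene, 597 genes were at least 2-fold higher and 760 at least 2-fold lower, so that the share of higher genes among them went from 19.4% to 44.0%. At 4-fold, 142 genes were higher and 154 lower on this relative scale. Probe sets of 1 gene lay on opposite sides of 0 for 31 of the 727 2-fold genes that had several.

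**Figure D1:**
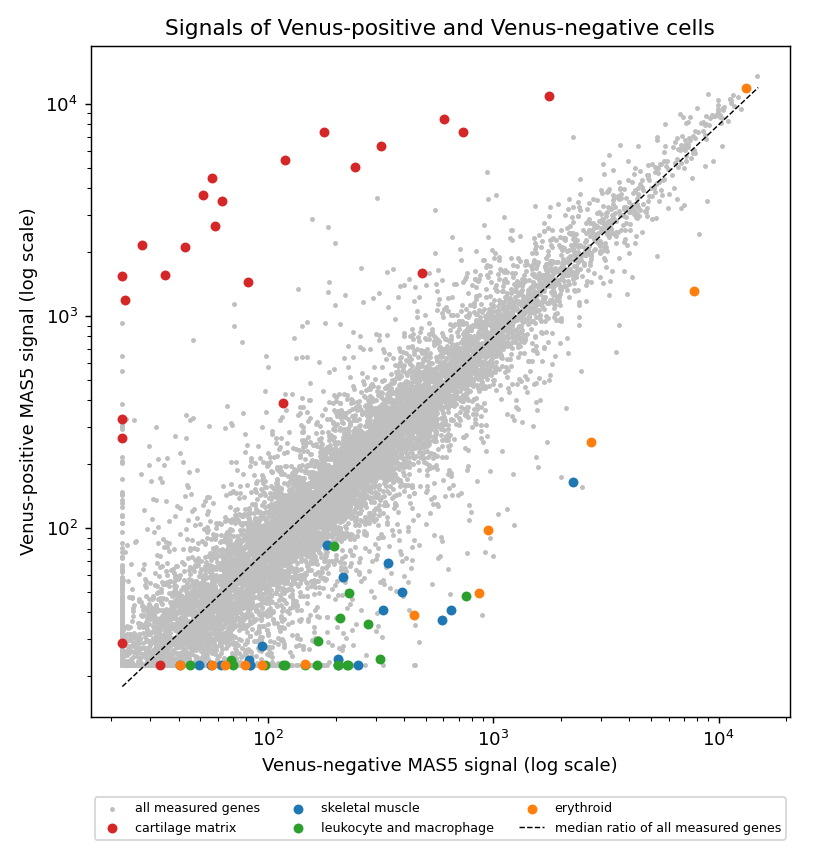
MAS5 signal of each measured gene in Venus-positive cells against that in Venus-negative cells, both on log scales, with signals below the floor drawn at 22.5. Cartilage matrix genes lie above the dashed line of the median ratio, except Cilp, and skeletal muscle and leukocyte genes lie below it.

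Genes of the cartilage matrix were the highest in Venus-positive cells. Of the 23 measured members of this list, 21 were at least 2-fold higher and none was 2-fold lower on either scale, with a median relative log2 ratio of 4.70. Matn1, which encodes matrilin 1, had a signal of 4478 in Venus-positive and 56.3 in Venus-negative cells, 79.5-fold higher. Comp (cartilage oligomeric matrix protein) was 78.4-fold, Epyc (epiphycan) 72.8-fold and Acan (aggrecan, the main cartilage proteoglycan) 55.3-fold higher. Matn3 was below the floor in Venus-negative cells and at least 68.1-fold higher. The 15 genes with the largest excess also included Snorc (51.4-fold), Susd5 (49.4-fold), Cytl1 (45.7-fold), Hapln1 (45.5-fold), Col11a2 (44.7-fold), Cnmd (41.7-fold) and Matn4 (20.6-fold), all in the cartilage matrix list. The remaining 3, each below the floor in Venus-negative cells, were the channel gene Panx3 (at least 41.0-fold), the Wnt receptor gene Fzd9 (at least 28.6-fold) and Scrg1 (at least 24.3-fold). The 4 measured probe sets of Hapln1, the cartilage link protein, gave 44.1- to 52.2-fold. Panx3 rests on 1 probe set, since its second was at 33.8 in Venus-positive cells, close to the floor. Col2a1 itself was 13.9-fold higher (8443 against 606), which checks the sort and is no independent finding, because the reporter was used to choose the cells. The 2 genes measured without a 2-fold difference, once the floor was applied, were Ucma (28.6 against 6.83) and Cilp (8.77 against 33.2). No random list of the same size and brightness among 10000 had a median as high as that of this list.

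**Figure D2:**
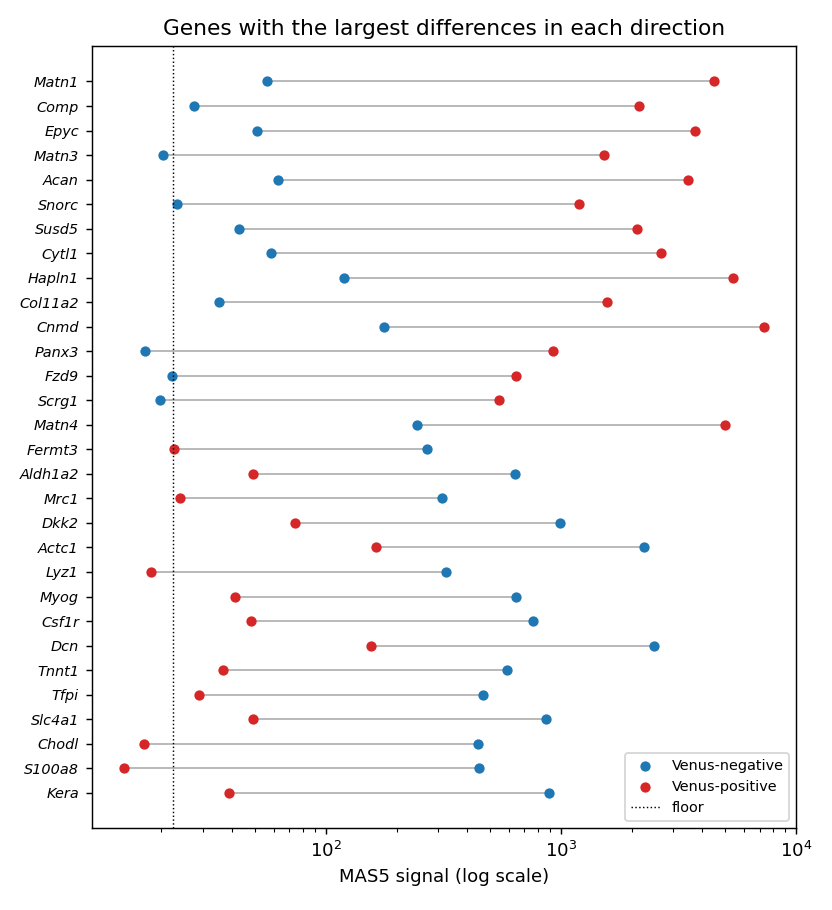
MAS5 signals, on a log scale, of the 15 genes with the largest difference in each direction, with the Venus-negative value in blue and the Venus-positive value in red. Points left of the dotted line lie below the floor of 22.5, as for Matn3, Panx3, Fzd9 and Scrg1 in Venus-negative cells, and their folds are lower bounds.

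Sox9, the transcription factor required for cartilage formation, had a signal of 1601 in Venus-positive and 338 in Venus-negative cells, 4.73-fold higher, and its second measured probe set gave 4.78-fold. Among the 26 measured transcription factors linked to cartilage, 8 were at least 2-fold higher, 2 were 2-fold lower and 16 were neither, against 12 higher and 2 lower relative to the median gene. A probe set of Sox5 gave a log2 ratio of 0.12 and one of Arid5b -0.89. The median relative log2 ratio was 0.90, above all 10000 matched random lists. Sox5 (5.77-fold) and Sox6 (4.42-fold), the partners of Sox9 in activating matrix genes, were among the higher genes, as were Runx3 (5.96-fold), Foxc2 (5.56-fold) and Foxc1 (4.12-fold). The 2 lower genes were Arid5b (3.36-fold) and Lmx1b (3.82-fold). In the forkhead family 4 of 25 measured genes were at least 2-fold higher and 2 were 2-fold lower, with a median relative log2 ratio of 0.39 at percentile 99.95 of the matched lists. The 2 lower genes, Foxn3 (2.37-fold) and Foxp1 (2.07-fold), were within 2-fold relative to the median gene. The 4 higher genes were Foxc2, Foxc1, Foxd1 (3.54-fold) and Foxa3, at least 4.70-fold higher from below the floor.

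The machinery that sulfates and assembles matrix glycosaminoglycans was higher in Venus-positive cells. Of 21 measured genes 8 were at least 2-fold higher (11 on the relative scale) and none was 2-fold lower, and all 21 lay above the median gene, with a median relative log2 ratio of 1.14. Papss2, which makes the sulfate donor, was 11.9-fold higher (3608 against 304), the chondroitin sulfotransferase gene Chst11 was 7.79-fold, the sulfate transporter gene Slc26a2 was 6.06-fold and Extl1 was at least 6.41-fold higher. Other probe sets of Papss2 and Slc26a2 gave log2 ratios down to 2.20 and 1.10. Collagen folding and secretory pathway genes had a median relative log2 ratio of 0.91, and 7 of 27 were at least 2-fold higher (13 on the relative scale) and none lower. These included the collagen prolyl 4-hydroxylase subunits P4ha2 (5.15-fold) and P4ha1 (3.25-fold), the lysyl hydroxylase gene Plod2 (3.03-fold) and the retention receptor gene Kdelr3 (2.63-fold), while the chaperone gene Hspa5 was level on the deposited scale (8746 against 8749). Hypoxia and glycolysis genes had a median relative log2 ratio of 0.98. Of 21 measured, 3 were at least 2-fold higher on the deposited scale, P4ha1, Hk2 (hexokinase 2, 3.16-fold) and Bnip3 (2.78-fold), and none was lower. On the relative scale 10 were higher. The glucose transporter gene Slc2a1 was 1.98-fold and Car9 at least 1.98-fold higher. These 3 list medians were above all 10000 matched random lists, and P4ha1 is a member of both of the last lists. With the floor at the 75th percentile of all signals, the glycosaminoglycan list's median log2 ratio on the deposited scale was 0.43 in place of 0.80.

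Genes of maturing, prehypertrophic and hypertrophic chondrocytes were also higher. Of 12 measured members, 6 were at least 2-fold higher (8 on the relative scale) and none lower, and all 12 lay above the median gene, with a median relative log2 ratio of 1.33 that exceeded all matched random lists. Apart from Panx3, the higher genes included Ihh, the hedgehog ligand of the growth plate (170.0 against 16.3, at least 7.56-fold), Sp7 (at least 4.25-fold) and Ibsp (3.02-fold). Col10a1, the collagen of hypertrophic cartilage, reached a signal of only 48.1 and was at least 2.14-fold higher. In the osteoblast list 3 of 11 measured genes were at least 2-fold higher, Ifitm5 (4.33-fold), Sp7 and Ibsp, and Phex was at least 6.45-fold lower. On the relative scale 6 were higher and 1 lower. The abundant bone collagen genes Col1a1 (1189 against 1900) and Col1a2 (5845 against 7892) had relative log2 ratios of -0.34 and -0.10. Of the 3 measured probe sets of Col1a2, the lowest gave a log2 ratio of -1.91 on the deposited scale. The median relative log2 ratio of the osteoblast list was 1.11, above all matched random lists. With the higher floor, which removes its dim members, its median on the deposited scale turned from 0.78 to -0.29, at percentile 20.7, so the direction of this list rests on genes of low signal.

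Signalling genes differed in both directions. Fgfr3, a receptor of chondrocytes, was 11.2-fold higher in Venus-positive cells (2214 against 198), though its second probe set gave a log2 ratio of 1.52 against 3.48. Fgfrl1 was 3.57-fold and Fgfr2 2.64-fold higher, while the feedback inhibitor gene Spry1 was 3.22-fold, Fgf9 at least 2.92-fold and Fgf18 2.24-fold lower. Over 16 measured FGF genes, 3 were 2-fold higher and 3 lower on the deposited scale and 6 higher and 2 lower on the relative scale, with a median relative log2 ratio of 0.48 at percentile 99.91. On the deposited scale the sign of this median turned, from 0.15 to -0.0076, when probe sets prone to cross-hybridisation were left out, while its percentile was still 98.8. Among 23 BMP and GDF genes 6 were at least 2-fold higher and 1 was 2-fold lower, against 10 and none on the relative scale, with a median relative log2 ratio of 0.62, above all matched lists. Gdf10 was 2.90-fold, Bmp5 2.64-fold and the receptor gene Bmpr1b 2.61-fold higher, and Fst (follistatin) was 2.39-fold lower on the deposited scale and within 2-fold of the median gene on the relative scale. In the hedgehog list Ihh and the target and receptor gene Ptch1 (3309 against 1528, 2.17-fold) were at least 2-fold higher, and Gli1 was at 156 against 97.8 and Gas1 at 3229 against 5987. The hedgehog median was -0.06 on the deposited scale and 0.28 on the relative scale, at percentile 96.0. Of 25 Wnt genes 8 were at least 2-fold lower and 3 higher on the deposited scale, and 4 lower and 4 higher on the relative scale. Their median relative log2 ratio was -0.25 at percentile 0.55, and the percentile was 31.6 with the floor at the 75th percentile and 18.2 without probe sets prone to cross-hybridisation. The Wnt antagonist gene Dkk2 was 13.4-fold lower (73.9 against 993), Rspo3 was 3.60-fold and Ror1 2.93-fold lower. The 3 higher genes were Fzd9, Frzb (2.90-fold) and Sfrp5 (at least 2.02-fold). A second probe set of Ror1 gave a log2 ratio of -0.06, one of Ptch1 0.25 and one of Bmpr1b 0.78.

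Marker lists of 5 other cell types had lower medians in Venus-positive cells. All 18 leukocyte and macrophage genes lay below the median gene, with 17 at least 2-fold lower on the deposited and 16 on the relative scale, and a median relative log2 ratio of -2.16. Csf1r, the macrophage growth factor receptor gene, was 15.8-fold lower (48.0 against 758), Mrc1 was 13.1-fold and Tyrobp at least 10.0-fold lower. Lyz2 was at least 9.93-fold lower, but it and Lyz1 are close paralogs whose probes can share targets. All 19 measured skeletal muscle genes lay below the median gene and 18 were at least 2-fold lower (15 on the relative scale), with a median of -1.56. Among them were Tnnt1 (slow troponin T, 16.1-fold), Myog (myogenin, 15.8-fold), Actc1 (13.8-fold) and Myh3 (at least 11.1-fold). In the erythroid list 10 of 12 were at least 2-fold lower (9 on the relative scale), with a median of -1.98. Slc4a1, the red cell anion exchanger gene, was 17.6-fold, Alas2 11.4-fold, Hbb-bh1 10.7-fold and Car2 9.65-fold lower, whereas the embryonic globin gene Hbb-y was nearly level (11912 against 13190) at signals close to the highest on either array. Epithelial and epidermal genes had a median of -1.71 with 11 of 15 at least 2-fold lower (10 on the relative scale), including Cdh1 (E-cadherin, 8.51-fold), Krt14 (at least 8.13-fold), Trp63 (at least 6.38-fold) and Dsp (5.61-fold). Endothelial genes had a median of -1.44 with 11 of 14 at least 2-fold lower (10 on the relative scale), including Plvap (at least 6.81-fold), Ecscr (5.58-fold), Emcn (5.34-fold) and Cdh5 (4.89-fold). These 5 medians lay below all 10000 matched random lists.

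In the fibroblast and perichondrium list 11 of 20 measured genes were at least 2-fold lower (8 on the relative scale) and none higher, with a median relative log2 ratio of -0.89. The proteoglycan gene Dcn (decorin) was 15.9-fold lower (156 against 2483), Dpt at least 6.66-fold, Osr1 5.62-fold and Postn (periostin) 5.16-fold lower. Col3a1 was also lower, at 6301 against 10341 on its probe set with the highest mean log2 signal. Smooth muscle and pericyte genes had a median of -1.30 with 5 of 9 at least 2-fold lower, among them Acta2 (11.5-fold), Abcc9 (at least 4.91-fold), Actg2 (at least 4.65-fold), Tagln (3.49-fold) and Rgs5 (3.10-fold). Cspg4, a proteoglycan gene used as a pericyte marker, was 12.7-fold higher. Both medians were below all matched lists. Without probe sets prone to cross-hybridisation, which leaves out Acta2, the smooth muscle median on the deposited scale was -0.65 in place of -1.63, at percentile 5.44, so this call rests on such probe sets. Other probe sets of Abcc9, Rgs5, Ednrb and Afp gave log2 ratios of -0.39, -0.41, -0.32 and -1.83. Neuronal genes had a median of -0.34 at percentile 2.88, with 7 of 15 at least 2-fold lower (5 on the relative scale), such as Nefl (5.34-fold), Nefm (5.08-fold), Gap43 (4.79-fold) and Stmn2 (3.28-fold). Under the alternatives the percentile of the neuronal list ran from 0 with the floor at the 25th percentile to 6.4 with it at the 75th. In the list for neural progenitors, glia and neural crest 3 of 8 measured genes were at least 2-fold lower (2 lower and 1 higher on the relative scale), Ednrb (at least 9.32-fold), Nes (2.71-fold) and Fabp7 (2.46-fold). Sox2 was at 3.63, below the floor, against 41.8, at least 1.86-fold lower. Of 5 measured hepatocyte genes Afp (at least 9.90-fold) and Alb (at least 4.83-fold) were lower, and Ttr was at 55.1 against 34.6. Apoa1 was at 4.58, below the floor, against 29.1, at least 1.29-fold lower. The medians of the last 2 lists were at percentiles 15.2 and 20.2. Under the alternatives the percentile of the neural list ran from 4.45 to 86.45, the latter with the floor at the 25th percentile. The hepatocyte median on the deposited scale moved from -0.37 to -1.12 with quantile normalization, at percentile 0.74, where 4 of its genes were measured, so neither list has a settled place. Medians of dim lists depended on the floor. With the floor at the 75th percentile the deposited-scale medians of the endothelial and leukocyte lists were -0.35 and -0.85 in place of -1.77 and -2.49. The endothelial one, over 4 genes, was then at percentile 8.82. The epithelial median, over 8 genes, was -0.88 in place of -2.04, at percentile 0.03.

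The 15 genes with the largest deficit in Venus-positive cells included members of several lists and genes in none of them. Kera (keratocan), a proteoglycan gene of tendon and cornea, was 22.96-fold lower (38.9 against 894). S100a8, a neutrophil gene (13.8 against 450), and Chodl (16.9 against 442, at least 19.6-fold lower) were below the floor in Venus-positive cells, so the order of these 3 genes is not settled. Slc4a1, Tfpi (tissue factor pathway inhibitor, 16.1-fold), Tnnt1, Dcn, Csf1r, Myog, Lyz1 (at least 14.4-fold), Actc1, Dkk2, Mrc1, Aldh1a2 (13.04-fold) and Fermt3 (12.0-fold) completed the 15. The smaller differences of further probe sets, -1.67 for Csf1r, -2.79 for Lyz1, -0.87 for Tfpi and -0.47 for Fermt3 on the log2 scale, came from dimmer probe sets of those genes.

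In the limb mesenchyme list 11 of 17 genes were at least 2-fold lower (7 on the relative scale) and none higher, with a median relative log2 ratio of -0.89, below all matched lists. Msx1 was 4.93-fold, Prrx2 3.85-fold, Lhx2 3.84-fold and Twist1 3.31-fold lower. Of 27 measured Hox genes 8 were at least 2-fold lower on the deposited and 4 on the relative scale, and none was higher, with a median of -0.33 at percentile 0.38. Hoxb3 was 6.38-fold, Hoxc5 at least 5.16-fold, Hoxd13 3.95-fold and Hoxc8 2.92-fold lower, with a log2 ratio of -0.66 from a second probe set of Hoxb3. In the sclerotome and somite list Foxc2 and Foxc1 were higher, and Meox2 (5.20-fold), Meox1 (3.87-fold) and Twist1 were lower, with the median of 11 genes at percentile 5.76, which was 62.99 without a floor and 62.4 with the mean over probe sets, so this list has no settled place either. Tendon and joint genes split, with 5 of 14 at least 2-fold lower (4 on the relative scale) and 3 higher, and a median of -0.28 on the deposited and 0.05 on the relative scale, at percentile 65.0. The tendon genes Kera, Tnmd (tenomodulin, 7.29-fold), Thbs4 (6.82-fold), Col14a1 (2.57-fold) and Scx (at least 2.32-fold) were lower, and Tnc (2.88-fold), Gdf5 (2.32-fold) and Fmod (2.02-fold) were higher. In the notochord list, whose median was -0.26 on the deposited and 0.07 on the relative scale, at percentile 45.6, Car3 was 3.04-fold and Krt8 2.02-fold lower, and Krt18 was at 96.5 against 142. Foxa2 was at 29.7 against 1.54, the latter below the floor, so it was at least 1.32-fold higher. Probe sets of Car3 and Scx gave log2 ratios of -0.24 and -0.38 and one of Fmod 0.50.

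**Figure D3:**
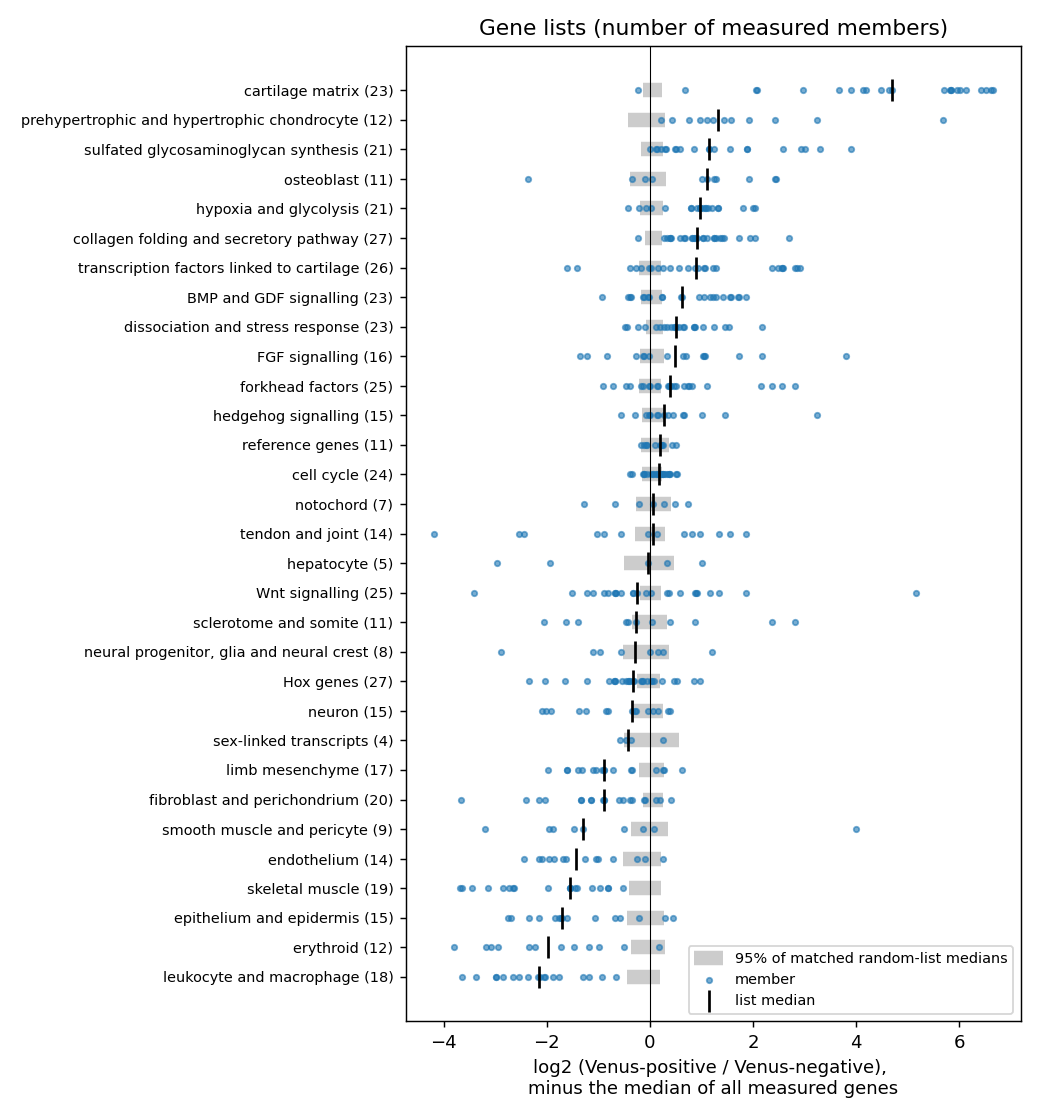
Relative log2 ratio of each measured member (points) and the median (bar) of the 31 gene lists, with grey bands for the central 95% of medians of 10000 random lists matched on size and signal. The cartilage matrix median of 4.70 lies farthest to the right and the leukocyte and macrophage median of -2.16 farthest to the left.

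Cell cycle and reference genes differed little. None of 24 cell cycle genes and none of 11 reference genes differed by 2-fold on either scale. The cell cycle median was -0.16 on the deposited and 0.17 on the relative scale, at percentile 91.8. Bub1 (416 against 688), Ccnb2 (373 against 596) and Rrm2 (1231 against 1695) had relative log2 ratios of -0.39, -0.34 and -0.13. Tyms (16.9 against 30.8) was below the floor in Venus-positive cells, so its relative log2 ratio of -0.12 is only a bound set by the floor. The reference gene median likewise changed sign with the scale, from -0.13 to 0.20, at percentile 81.5, and Sdha (652 against 925), Ywhaz (3126 against 4240), B2m (1013 against 1354) and Tbp (144 against 188) had relative log2 ratios of -0.17, -0.11, -0.09 and -0.05. Genes of the dissociation and stress response had a median relative log2 ratio of 0.51 at percentile 99.99. Of 23 genes 3 were at least 2-fold higher (5 on the relative scale) and none lower, namely Klf2 (3.58-fold), Ier3 (2.29-fold) and Junb (2.17-fold), while Nr4a1 was 1.88-fold higher. The immediate early gene Fos was at 6896 in Venus-positive and 6518 in Venus-negative cells. The ratio of 3' to 5' probe sets, a sign of RNA quality, was 1.64 for beta-actin in Venus-positive and 1.33 in Venus-negative cells, and 0.74 and 0.76 for Gapdh. Of the sex-linked transcripts, Uty (61.5 against 116), Eif2s3y (217 against 377) and Kdm5d (123 against 199) are from the Y chromosome. Their relative log2 ratios were -0.58, -0.47 and -0.37, and that of Xist (1681 against 1787) was 0.24. Other probe sets gave deposited-scale log2 ratios up to -0.18 for Uty and down to -0.73 for Xist. The median of these 4, which mixes Xist with Y-linked genes, was at percentile 4.02. With the floor at the 75th percentile it was at 16.4.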

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

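Outside the named genes, measured probe sets without a single gene name also differed between the fractions, with the Venus-negative array as the control. This count was not among the choices made in advance. Of 3353 such probe sets, 5 were at least 4-fold higher and 31 at least 4-fold lower in Venus-positive cells on the deposited scale, against 12 and 16 relative to the median gene. They stand outside the gene comparison because their annotation gives several genes or none. The largest excess was at least 7.17-fold (161 against 17.7) and the largest deficit at least 19.5-fold (18.1 against 438). With 1 array per group, a comparison of samples within a group was not possible.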

How the results depend on the processing

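Of the settings compared here, only the scaling to the hybridisation controls was chosen after seeing the data. The list percentiles under each setting were also added then, and with 1 array per group no replicate could be left out. No paired analysis was possible because each group has 1 array. Values are counts of genes and median log2 ratios on each setting's own scale, and where a value moved the cause was not tested unless stated. The log2 ratio of Col2a1 ranged from 3.77 to 4.13. Among the 133 genes named by the fixed rule, none that differed by at least 2-fold turned its sign in any setting in which it was measured. Centring could not turn such a gene, and the genes named for contrast were not part of this check. After centring on the median ratio, 597 genes were at least 2-fold higher, 760 at least 2-fold lower and 154 at least 4-fold lower, a change that follows from the subtracted shift. Quantile normalization gave 599, 766 and 169, and moved the medians for cartilage transcription factors to 0.93, osteoblast to 1.17, forkhead factors to 0.45, Hox genes to -0.28, sclerotome and somite to -0.16, smooth muscle to -1.22, endothelium to -1.36 and hepatocyte to -1.12. The floor sets how far a difference from a dim signal can reach. With it at the 25th percentile, 672 genes were 2-fold higher, 2534 lower, and 164 and 628 differed by 4-fold, and medians were 4.996 for cartilage matrix, -2.92 for skeletal muscle, -2.97 for erythroid, -3.09 for leukocyte, -1.49 for neuron and -0.13 for neural progenitor genes. With it at the 75th percentile the counts were 181, 475, 51 and 60. Medians were then 3.80 for cartilage matrix, 0.63 for hypertrophic chondrocyte, -0.29 for osteoblast (turned from 0.78), 0.43 for glycosaminoglycan, -1.50 for skeletal muscle, -1.02 for smooth muscle, -0.35 for endothelium, -0.85 for leukocyte, -0.18 for neural progenitor, -0.88 for epithelium, -0.97 for hepatocyte and -0.39 for sex-linked genes. Without a floor, medians were -0.23 for sclerotome, -1.26 for smooth muscle, -1.34 for endothelium, -0.062 for neural progenitor and -1.51 for epithelium. The mean over probe sets gave -1.02 for smooth muscle. Without probe sets named _x_at or _s_at, FGF genes were at -0.0076 (turned from 0.15), smooth muscle at -0.65 and hepatocyte at -1.27. Scaling to the hybridisation controls gave 519 and 875 genes 2-fold higher and lower, and -1.19 for hepatocyte. Percentiles after centring were fixed in advance, since subtracting 1 value from all ratios cannot change them. Of the 21 lists outside the central 95% of matched lists, 4 came inside it in 5 of 168 values, those after centring included: osteoblast, Wnt and endothelium with the higher floor, and Wnt and smooth muscle without the _x_at and _s_at probe sets. Hedgehog, neuron and hepatocyte genes went outside it in 9 values. The other list medians moved by less than 0.35, though subtracting the median ratio of -0.33 could not count as a move, and scaling by the control median of -0.27 hardly could. Among them the hedgehog, cell cycle and reference gene medians, below 0 on the deposited scale, were above 0 after centring, quantile normalization and scaling to the controls, tendon and joint after the first 2 of these, and notochord after centring.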

Other observations

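The tests in this part were chosen after the results had been seen, and so were the genes of the first 2 paragraphs. Several genes outside the lists had large excesses in Venus-positive cells. Mia (melanoma inhibitory activity, also known as a cartilage-derived protein) was 18.4-fold higher (2868 against 156), Scin (scinderin, an actin-severing protein) 16.7-fold, Lgals3 (galectin 3) 16.2-fold and Wwp2, whose locus also hosts a cartilage microRNA, 14.3-fold, though the lowest of the 5 probe sets of Wwp2 gave a log2 ratio of 1.27 against 3.84. The calcium-binding protein gene S100b was at least 13.6-fold higher, and the cation channel gene Trpv4 was at 202 against 14.7. Sox8, a close relative of Sox9, was at least 9.16-fold higher from a signal below the floor. Other matrix and adhesion genes included Chadl (7.89-fold), Mgp (matrix Gla protein, 5.78-fold), C1qtnf3 (5.72-fold), Cthrc1 (5.12-fold) and the collagen-binding integrin gene Itga10 (at least 5.61-fold).

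Further single genes had lower signals in Venus-positive cells, and no group of genes was tested here. Among them were Srgn (serglycin, 11.9-fold), Cpa3 (carboxypeptidase A3, 9.76-fold), Igfbp3 (9.40-fold), Egfl6 (9.04-fold), the retinoic acid receptor gene Rarb (7.58-fold), Vegfc (7.49-fold) and Igf1 (4.99-fold), and S100a9 was at least 10.5-fold lower. Crabp1 and Crabp2, genes of retinoic acid binding proteins, were at 548 against 2452 and 358 against 1566. Cyp26b1, a gene of retinoic acid breakdown, was at 360 against 196, and Dhrs3 was level on the deposited scale (159 against 163).

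The typical gene was lower on the Venus-positive array, by 0.33 on the log2 scale. Signal taken up by the much higher genes argues poorly for this, since the 103 genes at least 4-fold higher held 0.24% of summed signal in Venus-negative and 2.95% in Venus-positive cells, which would lower the others by only -0.040 on the log2 scale. The 18 hybridisation control probe sets, whose transcripts are added in fixed amounts, had a median log2 ratio of -0.27 (SD 0.10 over probe sets), and all 18 were lower. An array brightness that was not scaled to a shared target is therefore the candidate explanation. Which scale is better for genes near 0 was not tested. The reference gene median was -0.13 on the deposited and 0.20 on the relative scale. The 24 poly-A control probe sets had a median of -0.52, for which no explanation was tested.

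The matrix genes did not differ by a common factor. Among the 18 that were above the floor on both arrays and at least 2-fold higher, log2 ratios ran from 1.72 for Col27a1 to 6.31 for Matn1. Brightness alone did not order these ratios. Col27a1 and Hspg2, with the lowest ratios (1.72 and 1.74), had Venus-positive signals of 1589 and 387. Among brighter genes Cnmd (7343) had 5.38, but Col9a1 (10902) had 2.63 and Col2a1 (8443) 3.80. Comparing probe sets of 1 gene could not tell compressed signal at the bright end apart from other causes. Over the 7 of the 18 genes with several probe sets above the floor on both arrays, the log2 ratio of the brightest minus that of the dimmest set had a median of 0.036, against a pooled SD of 0.35 between probe sets of 1 gene. The difference was below 0 for Col9a1 (-1.68), Col27a1 (-1.27) and Col9a3 (-0.33) and above 0 for Hspg2 (0.95), Col11a1 (0.23), Hapln1 (0.05) and Susd5 (0.04). Labelled cells left in the Venus-negative fraction, if like the sorted ones, would alone give these genes about the same ratio. The SD of 1.49 over the 18 genes, against the pooled SD of 0.35, argues against left-over cells alone as the whole cause. Left-over cells together with compressed signal stay open, since probe sets of Col9a1 alone differed by -1.68. Low levels of these transcripts in the fraction's own cells, with or without such left-over cells, may contribute and were not tested.

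Among the embryonic globin genes, Hbb-y was nearly level (11912 against 13190) while Hba-x was 5.91-fold and Hbb-bh1 10.7-fold lower. Saturated signal could hide a difference in Hbb-y, whose signals were near the highest on either array. The dimmest of its 3 probe sets was 1.48-fold lower and the brightest 1.11-fold lower, a log2 difference of -0.42 in the direction saturation predicts, above the pooled SD of 0.35 between probe sets of 1 gene but by too little to decide. For red cells carried over into the Venus-positive fraction, the 9 other measured erythroid genes were compared. They had a median log2 ratio of -2.06 (SD 1.11 over genes), which is -1.91 from that of Hbb-y. Red cells with the same transcripts as those of the Venus-negative fraction would, carried over, give all these genes about 1 ratio. All 3 Hbb-y probe sets (log2 ratios -0.15 to -0.57) lay above the highest of the 9 genes (-0.84). These values argue against carry-over of such cells alone, although the ratio of Hbb-y may itself be saturated. Carry-over of red cells with other transcripts stays open. Carry-over together with saturation, and targets shared with other globin genes, also stay open and were not tested, and no biological explanation was tested.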
